A study of Homo sapiens with 48 samples.

How the data were processed

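Human skin from formalin-fixed, paraffin-embedded blocks was profiled with the NanoString GeoMx Digital Spatial Profiler, an assay in which probes against the transcriptome carry tags that light releases from a chosen region of a section, so that the tags of that region can be counted by sequencing. Per the labels, the sections were stained for pancytokeratin (epithelium), nuclei, CD138 (the plasma cell surface protein syndecan, gene SDC1) and CD31 (the vessel protein PECAM1), and regions were taken from lesions of hidradenitis suppurativa (HS), cutaneous squamous cell carcinoma (SCC), benign infundibular cysts and healthy control skin. The 48 regions fell into 17 groups by the diagnosis and structure in their labels, and replicate numbers only name the regions of a group. The labels count 4 donors with HS, 3 with SCC, 3 with a cyst and 3 healthy donors but tie no region to a donor.

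The deposited count files hold 1 region each and give deduplicated counts per probe, made with GeoMx NGS Pipeline 2.3.4 per the file headers, which name 1 plate and 1 sequencing set for all regions. The deposited table of the authors holds log2 values of 14243 genes and a negative-probe level (probes with no human target), scaled so that the upper quartile, back on the linear scale, was 85.23 in every region; how the authors chose these genes among the 18815 probes is not stated. The count files name no genes. A gene name was given to a probe only where the authors' values, returned from log2 to the linear scale and divided by 1 step per region, equalled the counts of exactly 1 probe in all 48 regions (100% of values whole within 0.0001). All 14243 genes found a probe, 235 of them only after a count of 0 was read as 1, and 4572 probes stayed unnamed and took 3.25 to 14.74% of a region's counts. In the reference list of symbols, 14058 of the names were current, 179 were synonyms and 6 were absent. As these are human samples, 11 sex-linked genes were left out, which left 14232 genes.

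Counts were tested with edgeR 4.0.16 under R 4.3.3 (TMM scaling factors, filterByExpr with a minimum count of 10, quasi-likelihood F tests), in 1 fit over the epithelial groups and 1 over the stromal groups. The filter removed no gene. For tunnel regions the coefficient was the mean of the mid and deep tunnel coefficients, so both depths weighed equally. P-values were adjusted by Benjamini-Hochberg over the genes of a comparison, with a threshold of 0.05, and "edgeR adjusted p" names them throughout; "changed", "rose" and "fell" are used of genes past that threshold. Log2 fold changes stand with their SE, computed from the F statistic, and mean levels in CPM, each count scaled to a common library total with the TMM factors of the fit, with their SD over regions. The fits held no batch term. A slide block was fitted as an alternative for tunnel and HS epidermis against healthy epidermis, tunnel against HS epidermis and deep against mid tunnel. It could not be fitted as a fixed term elsewhere between diagnoses: HS regions shared no slide with SCC or cyst regions, and SCC and cyst regions shared none with healthy skin. The HS regions came from 4 donors and were treated as independent although some share a donor, so edgeR p-values can be too small where HS is compared with SCC, cyst or healthy tissue, and too small or too large within HS, by an unknown amount.

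The 13 comparisons, their tests, 30 gene lists and the rule for naming genes were fixed before the data were examined. The rule names the 10 largest log2 fold changes in each direction among changed genes whose mean CPM in the higher group was at least 2 times the negative-probe level there, up to 4 members with the smallest p of each list described, and KRT5, KRT14, COL1A1, SDC1 and PECAM1 as checks of region identity. Each list was tested with camera (edgeR, with limma 3.58.1) at a preset correlation between genes of 0.01, and again with the correlation estimated from the data, adjusted over the lists of a comparison. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone.

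Similarity of tunnel epithelium to SCC and to cyst wall was the Pearson correlation, across genes, of log2 CPM (prior count 2) with each group's mean profile. The difference of the 2 was taken for each of the 11 tunnel regions, and the value is the mean of the mid and deep tunnel means, weighted equally. It was tested by exact permutation, two-sided, of the 6 SCC and cyst wall labels (20 assignments, smallest possible p 0.1). Fold changes against healthy epidermis were correlated across genes between disease groups, beside 20 simulations in which both groups were drawn without a difference from the same controls, since shared controls alone give a correlation.

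Total counts ran from 134665 to 10949664 (median 2311136.5), and the median gene stood 1.21 to 4.57 times above the negative-probe level, so the lower-expressed genes lay near background. Of the 190 top genes over all comparisons, 81 averaged under 2 times the negative-probe level in their lower group, 9 of them at or below it. The fold changes of these genes include background. The biological coefficient of variation was 0.29 among epithelial and 0.22 among stromal regions. On simulated counts with the same depths and dispersions, 4-fold changes were recovered for 73 to 99% of genes over the comparisons, and 2-fold changes for 10 to 68%, with 0.9 to 9.3% of calls false. The lowest chi-square per degree of freedom between 2 regions of a group was 2.1 over 61 pairs, so no file repeated another.

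The alternatives were DESeq2 1.42.0, limma-trend on log2 of the authors' linear values with a pseudocount of 1, upper-quartile factors, no filter, genes above the median gene in place of a limit of quantitation (the count files do not identify the negative probes), only the groups compared, mid or deep tunnel regions alone, slide blocks or single slides, and each region of groups of 2 to 5 left out in turn (a lone region left in a group was assumed to vary like the other groups). Added after seeing the data were fits without regions under 200000 counts, limma-trend on background-subtracted CPM with a pseudocount of 10, limma-voom without a slide block, and the similarity without depth, background or plasma cell differences. Other splits of the regions were refitted with the same model, 100 at most per comparison. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The groups with 1 region (HS infundibulum, its stroma, cyst infundibulum and cyst CD31 rich) entered no comparison.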

Results

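The series asks how the epithelium lining the tunnels of hidradenitis suppurativa (HS) relates to squamous cell carcinoma (SCC) and to the wall of benign infundibular cysts. HS is a chronic inflammatory skin disease in which epithelial tunnels form under the skin, and SCC is a skin cancer of keratinocytes. Probe counts of 14232 genes were analysed in 48 regions of 17 groups. Healthy epidermis had 3 regions (134665 to 837780 counts each), HS epidermis 3 (1365616 to 8152274), HS mid tunnel 4 (1144813 to 5500108) and HS deep tunnel 7 (1210647 to 3014985). SCC epithelium had 3 regions (1063636 to 2293450 counts) and cyst wall 3 (169820 to 1657875). In the stroma, HS mid tunnel stroma had 3 regions (2196246 to 4129299 counts), HS deep tunnel stroma 3 (2369970 to 4273300), SCC stroma 3 (226721 to 332416) and cyst stroma 2 (366187 and 415440). HS stroma was also sampled as plasma cell poor (3 regions, 845420 to 3224374 counts), plasma cell rich (3 regions, 1606829 to 10949664) and CD31 rich (4 regions, 5364854 to 10902867). HS infundibulum (3360742 counts), HS infundibulum stroma (4080250), cyst infundibulum (2475684) and cyst CD31 rich (1207971) had 1 region each. The HS regions came from 4 donors, and the labels do not say which from whom. P-values over regions ignore this, and can be too small where HS is compared with SCC, cyst or healthy tissue and too small or too large within HS.

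Tunnel epithelium (11 regions) was compared with healthy epidermis (3 regions) to ask what sets the tunnel lining apart from normal skin. KRT6A, a keratin induced in wounded epidermis, averaged 20380 ± 10130 CPM in tunnels against 77.29 ± 48.32 in healthy epidermis. Its log2 fold change was 8.07 ± 1.8 (edgeR adjusted p = 0.0117), and the lowest tunnel region stood 54.1 times above the highest healthy one. S100A9, a subunit of the antimicrobial protein calprotectin, averaged 30750 ± 12060 against 240.1 ± 348.7 CPM (7.03 ± 1.48, edgeR adjusted p = 0.00802). The defensin gene DEFB4B averaged 4467 ± 6015 against 30.29 ± 5.14 CPM (7.04 ± 1.45, edgeR adjusted p = 0.00703). Other top genes were PI3 (an elastase inhibitor of inflamed epidermis, 7.51 ± 1.35), SERPINB4 (a protease inhibitor, 7.23 ± 1.2) and GJB2 (a gap junction protein, 6.85 ± 1.2). KRT16 (6.7 ± 1.59), KRT17 (6.38 ± 1.77), S100A8 (6.5 ± 1.37) and S100A7 (6.15 ± 1.38) completed the top 10. KRT2, a keratin of the upper epidermis, was lower in tunnels at 26.85 ± 20.63 against 2759 ± 3748 CPM (-6.62 ± 1.05, edgeR adjusted p = 0.000898). CCL27, the keratinocyte chemokine that draws T cells to skin, averaged 17.63 ± 3.826 against 241.5 ± 240.3 CPM (-3.79 ± 0.62, edgeR adjusted p = 0.00112). Also lower were CDHR1 (-3.65 ± 0.44), the desmosomal cadherin DSC1 (-3.43 ± 0.72), SYT8 (-3.03 ± 0.31), SERPINA12 (-2.98 ± 0.68) and TNFRSF19 (-2.88 ± 0.42). The epidermal keratin KRT77 (-2.72 ± 0.44), the laminin chain LAMB4 (-2.7 ± 0.33) and BTG4 (-2.82 ± 0.66) followed. The basal keratins KRT5 (0.34 ± 0.62, edgeR adjusted p = 0.819) and KRT14 (1.17 ± 0.84, edgeR adjusted p = 0.46) passed no threshold.

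Among the fixed lists, 8 of 13 measured wound keratin and small proline-rich genes rose in tunnels and 0 fell (13 rose, adjusted over the list alone). SPRR1B, a precursor of the cornified envelope, was among them at 5.52 ± 1.46. For wound keratins, camera gave adjusted p = 6.18e-14, and adjusted p = 0.149 with an estimated correlation. Antimicrobial and IL-17 response genes rose for 9 of 24 members (15 adjusted over the list alone), among them LCN2, which withholds iron from bacteria (5.48 ± 1.16), and ZC3H12A, an RNase that limits cytokine transcripts (1.97 ± 0.4). For antimicrobial genes, camera gave adjusted p = 2.34e-13, and adjusted p = 0.149 with an estimated correlation. Glycolysis and hypoxia genes rose for 4 of 18 members (12 adjusted over the list alone), namely HK2 (1.85 ± 0.46), ENO1 (2.33 ± 0.63), LDHA (2.64 ± 0.73) and TPI1 (1.82 ± 0.5). For glycolysis, camera gave adjusted p = 4.36e-07, and adjusted p = 0.489 with an estimated correlation. Plasma cell genes rose for 5 of 20 members (11 adjusted over the list alone), all of them immunoglobulin genes, such as IGHG1 (3.61 ± 0.85) and IGKC (2.52 ± 0.63). For plasma cells, camera gave adjusted p = 4.71e-07, and adjusted p = 0.211 with an estimated correlation. Suprabasal keratinocyte genes fell for 3 of 11 members (4 adjusted over the list alone). For suprabasal genes, camera gave adjusted p = 0.000849, and adjusted p = 0.489 with an estimated correlation. Of 10 basal genes 3 fell (4 adjusted over the list alone), among them KRT15 (-1.87 ± 0.48) and DST (-1.69 ± 0.47), while the cadherin CDH3 rose (3.64 ± 1.01). For basal genes, camera gave adjusted p = 0.144, and adjusted p = 0.86 with an estimated correlation. Interferon response genes passed for 0 of 27 members by edgeR (0 adjusted over the list alone), at a median log2 fold change of 1.36. For interferon genes, camera gave adjusted p = 0.000158, and adjusted p = 0.86 with an estimated correlation.

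In all, 675 genes differed between tunnel and healthy epithelium, 256 higher and 419 lower, a split that turned with slide as a fixed block. The count was 178 without healthy epidermis replicate 1, 441 without replicate 2 and 109 without replicate 3. Of the 20 top genes 8 kept the call without each of 7 regions left out in turn. KRT6A, KRT16 and KRT17 lost the call without any 1 of the 3 healthy regions, S100A9 without healthy replicate 3, DEFB4B without replicate 1 or 3 and CCL27 without replicate 1. BTG4 turned to 0.22 without healthy replicate 2. Most tunnel regions lay on other slides than healthy skin. With slide as a fixed block 763 genes changed (475 higher and 288 lower), 392 of them shared with the 675. Within slide 3_2 (2 tunnel and 3 healthy regions) 0 of 45 named genes reversed direction. Each tunnel depth had a single region there, so the spread came from the 3 healthy regions alone. The number of genes changed within that slide is therefore not read as a result. SERPINB4 in healthy epidermis and LAMB4 in tunnels averaged no more than the negative-probe level, and 8 of the 20 top genes, among them CCL27, lay under 2 times that level in their lower group. DESeq2 called 1261 genes, the authors' values 1218 (729 higher) and the deep tunnel regions alone 371.

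**Figure D1:**
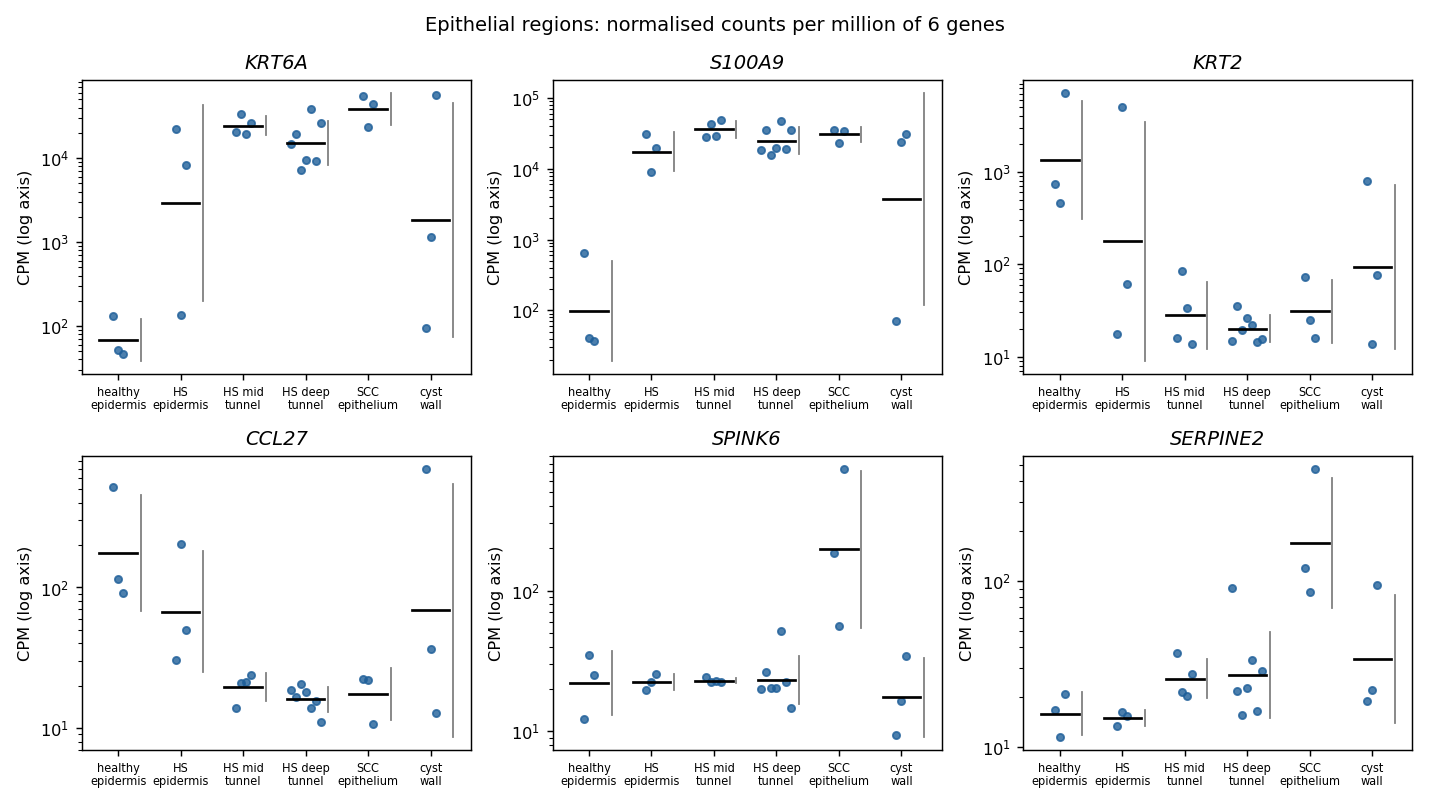
CPM (log axis, TMM-scaled) of KRT6A, S100A9, KRT2, CCL27, SPINK6 and SERPINE2 in each epithelial region by group; points are regions, the black line is the geometric mean and the grey bar spans 1 SD of log2 CPM on either side. KRT6A and S100A9 stood higher in the 11 tunnel and 3 SCC regions than in the 3 healthy regions, and SPINK6 averaged 323.5 CPM in SCC against 24.22 in tunnels and 20.03 in cyst wall.

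SCC epithelium (3 regions) was set against healthy epidermis (3 regions) to give the tumour's own difference from normal skin. KRT6A averaged 40590 ± 15690 CPM in SCC (9.01 ± 1.92, edgeR adjusted p = 0.0205), with the lowest tumour region 177 times above the highest healthy one. KRT16 (7.72 ± 1.72), KRT17 (7.4 ± 1.92), S100A9 (7 ± 1.53), PI3 (6.74 ± 1.35) and S100A8 (6.53 ± 1.43) followed. GJB2 (6.5 ± 1.23), SPRR1B (6.26 ± 1.58), CSTB, a cysteine protease inhibitor (5.83 ± 1.21), and S100A7 (5.46 ± 1.39) completed the top 10. KRT15, a keratin of basal and follicle stem cells, averaged 79.59 ± 37.27 against 1309 ± 910.9 CPM (-4.05 ± 0.75, edgeR adjusted p = 0.0101). The immunoglobulin light chain gene IGKC was lower in the tumour at 22.55 ± 3.965 against 261.8 ± 130.8 CPM (-3.55 ± 0.74, edgeR adjusted p = 0.0195). KRT2 (-6.17 ± 1.66), CDHR1 (-4.08 ± 0.7), CCL27 (-3.73 ± 0.95), TNFRSF19 (-3.42 ± 0.64) and IGHG4 (-3.25 ± 0.78) were lower too. So were the lipid carrier gene APOE (-3.03 ± 0.57), KRT77 (-2.81 ± 0.63) and LAMB4 (-2.74 ± 0.48). Wound keratin genes rose for 6 of 13 members (11 adjusted over the list alone). For wound keratins, camera gave adjusted p = 6.48e-14, and adjusted p = 0.278 with an estimated correlation. Antimicrobial genes rose for 4 of 24 (8 adjusted over the list alone, with 1 lower). For antimicrobial genes, camera gave adjusted p = 3.1e-05, and adjusted p = 0.668 with an estimated correlation. Of 24 invasion and matrix-remodelling genes 1 rose (8 adjusted over the list alone), SERPINE2, an inhibitor of thrombin and urokinase (3.67 ± 0.74). Fibronectin, FN1 (2.77 ± 0.76, edgeR adjusted p = 0.0524), and the protease gene MMP10 (3.32 ± 1.05, edgeR adjusted p = 0.0892) missed the threshold. For invasion genes, camera gave adjusted p = 2.13e-06, and adjusted p = 0.668 with an estimated correlation.

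In all 304 genes changed between SCC and healthy epithelium, 130 higher and 174 lower. The count was 68 without healthy epidermis replicate 1, 37 without replicate 3, 61 without SCC replicate 2 and 89 without SCC replicate 3. Of the 20 top genes 3 (KRT15, CDHR1 and TNFRSF19) kept the call in all 6 such fits, and KRT6A lost it without any 1 of the 3 healthy regions. Tumour and healthy regions shared no slide, so slide and tissue cannot be told apart here. DESeq2 called 799 genes, the authors' values 475 (301 higher), genes above the median gene 491 and a fit of only these groups 686 (383 higher and 303 lower). With upper-quartile factors the split was 167 higher and 137 lower, and without SCC replicate 1 or 2 it was 122 to 110 and 35 to 26. LAMB4 in the tumour averaged no more than the negative-probe level, and 8 of the 20 top genes lay under 2 times that level in their lower group.

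Of the genes changed against healthy epidermis, 57 were higher in both tunnel and SCC epithelium, and 130 were lower in both. A further 2 were higher in tunnel and lower in SCC epithelium. The tunnel and SCC lists rest on the same 3 healthy regions, and the overlap that these alone give was not computed. Across genes, which are not independent replicates, fold changes against healthy epidermis correlated at r = 0.816 between tunnel and SCC. The value was 0.622 between tunnel and cyst wall and 0.578 between SCC and cyst wall. Comparisons that share the 3 healthy regions correlate without any real likeness, and in simulated groups with no difference the same values were 0.699, 0.645 and 0.536. The covariance exceeded the simulated one by 0.263 for tunnel and SCC, 0.151 for tunnel and cyst wall and 0.139 for SCC and cyst wall.

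Cyst wall (3 regions) was compared with healthy epidermis (3 regions) as the benign counterpart of the tumour. The same wound keratins led by size, with KRT6A at 7.92 ± 1.84 (19000 ± 31840 CPM in cyst wall) and KRT16 at 6.8 ± 1.65. KRT6A was 94.42, 1155 and 55760 CPM in the 3 cyst regions, so replicate 3 carried its mean, and the first lay within the healthy range of 46.99 to 133. The glycolytic enzyme gene HK2 (2.29 ± 0.52) and the collagen gene COL3A1 (4.13 ± 1.01) stood beside them. Each had an edgeR adjusted p = 0.117, the smallest of the comparison. By edgeR 0 genes changed (1757 at an unadjusted p under 0.05), against 72 by DESeq2 (67 higher and 5 lower) and 203 on the authors' values (21 higher and 182 lower). Wound keratin genes passed for 0 of 13 (9 higher, adjusted over the list alone). For wound keratins, camera gave adjusted p = 5.96e-07, and adjusted p = 0.837 with an estimated correlation. Fibroblast and matrix genes passed for 0 of 18 (8 higher, adjusted over the list alone). For fibroblast genes, camera gave adjusted p = 5.1e-07, and adjusted p = 0.837 with an estimated correlation. The count was 306 without cyst wall replicate 1, the region with 169820 counts, and 4 without cyst wall replicate 2 or without healthy replicate 1. In simulated counts of this comparison 73% of 4-fold and 10% of 2-fold changes were recovered, and the groups shared no slide.

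Tunnel (11 regions) and SCC epithelium (3 regions) were compared directly to ask what separates them. Immunoglobulin genes, the products of plasma cells, were higher in tunnels. IGKC averaged 1454 ± 1097 against 22.55 ± 3.965 CPM (6.06 ± 0.79, edgeR adjusted p = 0.00029), and the lowest tunnel region stood 17.5 times above the highest tumour region. IGHG1 (6.06 ± 0.99), IGHG4 (5.95 ± 0.83), IGHG2 (5.78 ± 0.83), IGHG3 (5.51 ± 0.84), IGLL5 (4.01 ± 0.9) and IGHA1 (3.08 ± 0.63) followed. The IGHG genes are near-identical in sequence, so whether their probes tell them apart is uncertain. Outside this family NES (a filament of progenitor cells, 2.3 ± 0.5), EMP2 (1.73 ± 0.4) and NFKBIZ (a co-activator of IL-17 target genes, 1.6 ± 0.34) were higher in tunnels. SPINK6, an inhibitor of skin kallikreins, was lower in tunnels at 24.22 ± 9.423 against 323.5 ± 356.9 CPM (-3.76 ± 0.39, edgeR adjusted p = 1.61e-05). SERPINE2 averaged 30.5 ± 21.23 against 226.4 ± 214.1 CPM (-2.93 ± 0.43, edgeR adjusted p = 0.000796). KRT75, a keratin of the hair follicle, averaged 31.41 ± 7.589 against 189 ± 146.4 CPM (-2.58 ± 0.31, edgeR adjusted p = 9.58e-05). The cyclin gene CCND2 (-2.45 ± 0.56), the protease gene CTSV (-2.26 ± 0.48), FN1 (-2.08 ± 0.46) and RCAN1 (-1.96 ± 0.41) were lower as well. PPP2R2B (-1.96 ± 0.3), FAM131C (-1.9 ± 0.26) and IGFL2 (-1.82 ± 0.3) completed the list. KRT6A (-0.95 ± 1.03, edgeR adjusted p = 0.807) and KRT16 (-1.01 ± 0.97, edgeR adjusted p = 0.77) passed no threshold.

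Of 20 plasma cell genes 6 were higher in tunnels than in SCC (6 adjusted over the list alone), all of them immunoglobulin genes. For plasma cells, camera gave adjusted p = 1.05e-14, and adjusted p = 0.0381 with an estimated correlation. Of 24 antimicrobial genes 1 rose, NFKBIZ (4 adjusted over the list alone). For antimicrobial genes, camera gave adjusted p = 4.95e-05, and adjusted p = 0.54 with an estimated correlation. Of 24 invasion genes 2 fell, SERPINE2 and FN1 (3 adjusted over the list alone). For invasion genes, camera gave adjusted p = 0.000876, and adjusted p = 0.734 with an estimated correlation. In total 78 genes changed, 11 higher and 67 lower. The count was 45 without SCC replicate 1, 45 without replicate 2 and 121 without replicate 3. Of the 20 top genes 9 kept the call without each of 7 regions, namely IGKC, IGHG1 to IGHG4, SPINK6, SERPINE2, KRT75 and FAM131C. Tunnel and SCC regions shared no slide, so slide and diagnosis cannot be told apart. Other counts were 190 by DESeq2, 17 on the authors' values (10 higher), 18 and 48 with mid or deep tunnel regions alone, and 28 among genes above the median gene. IGHA1 averaged no more than the negative-probe level in SCC, and 13 of the 20 top genes lay under 2 times that level in their lower group.

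Set against cyst wall (3 regions), tunnel epithelium (11 regions) had 5 of 20 plasma cell genes and 2 of 24 antimicrobial genes higher (adjusted p = 0.0708 and adjusted p = 0.149 with an estimated correlation). DEFB4B averaged 4467 ± 6015 against 25.49 ± 18.82 CPM (7.4 ± 1.49, edgeR adjusted p = 0.0161) and PI3 10020 ± 8101 against 386.2 ± 347.1 CPM (4.74 ± 1.15, edgeR adjusted p = 0.0431). DEFB4B lost the call without cyst wall replicate 2 or 3, and PI3 without any 1 of the 3 cyst regions. IGKC averaged 1454 ± 1097 against 32.33 ± 7.69 CPM (5.55 ± 0.77, edgeR adjusted p = 0.000433). IGHG1 to IGHG4 (4.57 to 5.18), IGLL5 (4.32 ± 0.96), the plasminogen activator PLAT (4.57 ± 0.98) and the polyamine enzyme SAT1 (3.92 ± 0.89) were higher too. CCL27 was lower in tunnels (-3.68 ± 0.65, edgeR adjusted p = 0.00606), with 694, 36.41 and 12.84 CPM in the 3 cyst regions, and lost the call without replicate 1. DSC1 was lower too (-3.49 ± 0.72). PADI1, which citrullinates epidermal proteins (-2.78 ± 0.5), and BLMH, which breaks down filaggrin (-2.48 ± 0.56), were lower with them. CDHR1 (-3.33 ± 0.45), MUCL1 (-3.1 ± 0.42), TPPP3 (-2.73 ± 0.38), CRIP1 (-2.47 ± 0.55) and DAPL1 (-2.31 ± 0.51) also fell. TNFRSF11B, the decoy receptor osteoprotegerin, was lower (-5.27 ± 0.7, edgeR adjusted p = 0.000383), but at 0.74 without cyst wall replicate 1. Its tunnel mean of 12.87 CPM lay under the negative-probe level of 15.67, and 6 of the 20 top genes lay under 2 times that level in their lower group.

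Of 24 antimicrobial genes 2 rose in tunnels over cyst wall (12 adjusted over the list alone). For antimicrobial genes, camera gave adjusted p = 7.2e-13, and adjusted p = 0.149 with an estimated correlation. Plasma cell genes rose for 5 of 20 (9 adjusted over the list alone). For plasma cells, camera gave adjusted p = 7.2e-13, and adjusted p = 0.0708 with an estimated correlation. Interferon response genes passed for 0 of 27 by edgeR (0 adjusted over the list alone), at a median log2 fold change of 1.67. An example was IFI27 (3.33 ± 1.07, edgeR adjusted p = 0.122). For interferon genes, camera gave adjusted p = 9.68e-09, and adjusted p = 0.425 with an estimated correlation. Cornified envelope genes passed for 0 of 18 (2 lower, adjusted over the list alone), at a median of -1.48. For envelope genes, camera gave adjusted p = 3.25e-05, and adjusted p = 0.425 with an estimated correlation. Fibroblast and matrix genes, markers of another cell type, passed for 0 of 18 (12 lower, adjusted over the list alone), at a median of -1.12. For fibroblast genes, camera gave adjusted p = 6.08e-10, and adjusted p = 0.353 with an estimated correlation.

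For tunnel against cyst wall 164 genes changed, 32 higher and 132 lower, and this split depended on the scaling. With upper-quartile factors the count was 55 (27 higher, 28 lower), and on the authors' values, where the median gene itself moved by 0.149, it was 615 (540 higher, 75 lower). It was 89 without cyst wall replicate 2, 87 without replicate 3, 87 without mid tunnel replicate 1 and 105 without mid tunnel replicate 4. Of the 20 top genes 7 kept the call without each of 7 regions (IGKC, IGHG1 to IGHG4, CDHR1 and TPPP3). The slides of tunnel and cyst regions did not overlap. DESeq2 called 414 genes, mid and deep tunnel regions alone 35 and 61, and the fit without regions under 200000 counts (chosen after seeing the data) 339.

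The likeness of tunnel epithelium to each neighbour, the question of the series, was measured over the whole profile. The mean correlation of the 11 tunnel regions, with mid and deep tunnel weighted equally, was higher with the SCC profile than with the cyst wall profile by 0.0503. The difference was 0.0922 without cyst wall replicate 2, 0.0947 without replicate 3, and 0.0225 with every region thinned to one depth (chosen after seeing the data). Of the 11 tunnel regions 10 lay on the SCC side, with region values from -0.004 to 0.105. The exact permutation p, two-sided, was 0.2 over the 20 assignments of the 6 SCC and cyst wall labels, which cannot give less than 0.1. The jackknife SE was 0.0567, with each of the 6 SCC and cyst wall regions left out in turn and the values pooled. It holds no spread among tunnel regions. The difference did not exceed what other groupings of the same 6 regions gave, and the SCC and cyst wall profiles themselves correlated at r = 0.874. For scale, tunnel profiles drawn by simulation from the mean of the SCC group gave 0.118 and from that of the cyst group -0.106. Those are plain means over the 11 regions, and the profiles were compared with the groups they were drawn from. Tunnel regions shared no slide with either group.

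**Figure D2:**
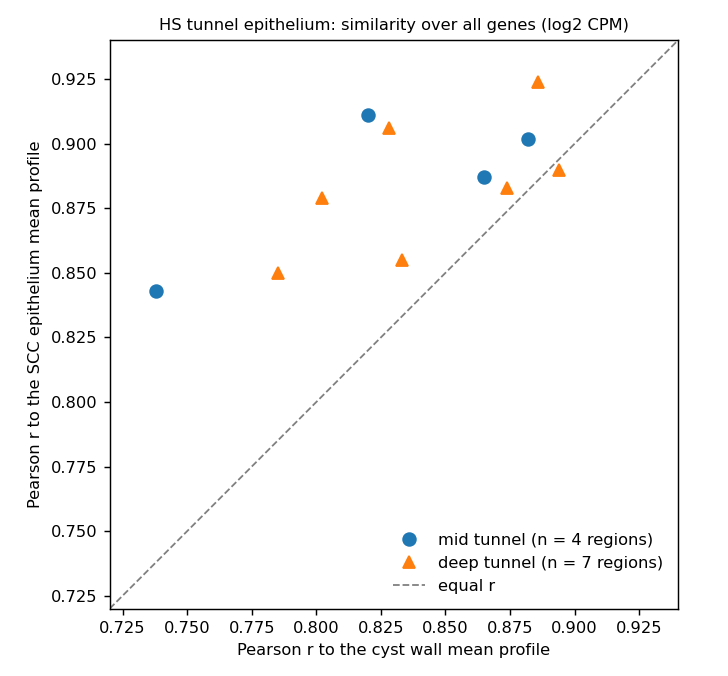
Each of the 11 tunnel regions (circles, 4 mid; triangles, 7 deep) by its Pearson r across genes with the mean cyst wall profile (x axis) and with the mean SCC profile (y axis); the dashed line marks equal r. Of the 11 regions 10 lie above the line, and the exact permutation p over the labels of the 6 SCC and cyst wall regions was 0.2.

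SCC epithelium and cyst wall (3 regions each) lay on 1 slide and were compared to separate malignant from benign epithelium. SPINK6 was higher in the tumour at 323.5 ± 356.9 against 20.03 ± 12.78 CPM (3.96 ± 0.66, edgeR adjusted p = 0.0308). KRT75 (2.68 ± 0.5), PPP2R2B (2.3 ± 0.49), FAM131C (2.24 ± 0.43), the basement membrane protein nidogen NID1 (1.56 ± 0.32) and the phospholipase PLA2G4A (1.4 ± 0.28) were higher with it. KRT15 was lower in the tumour at 79.59 ± 37.27 against 848.2 ± 312.5 CPM (-3.42 ± 0.73, edgeR adjusted p = 0.0471). CDHR1 (-3.76 ± 0.69), the WNT ligand gene WNT16 (-2.31 ± 0.49), IGSF9B (-1.82 ± 0.32), the clock gene DBP (-1.76 ± 0.35) and CRIP2 (-1.74 ± 0.34) were lower too. So were 4 near-identical deubiquitinase genes, USP17L11 (-3.26 ± 0.61), USP17L3 (-2.75 ± 0.57), USP17L15 (-2.68 ± 0.54) and USP17L17 (-2.6 ± 0.51). Interferon response genes passed for 0 of 27 by edgeR (0 adjusted over the list alone), with 26 values above 0 and a median of 1.37. For interferon genes, camera gave adjusted p = 1.18e-07, and adjusted p = 0.619 with an estimated correlation. Invasion genes passed for 0 of 24 (2 higher, adjusted over the list alone). For invasion genes, camera gave adjusted p = 4.77e-05, and adjusted p = 0.619 with an estimated correlation. In all 29 genes changed, 12 higher and 17 lower. The count was 54 without cyst wall replicate 1, 48 without replicate 2, 1 without SCC replicate 1, 2 without SCC replicate 2 and 108 (74 higher and 34 lower) without SCC replicate 3. Of the 16 top genes 1, SPINK6, kept the call without each of the 6 regions. Other counts were 270 by DESeq2, 154 on the authors' values (136 higher), 11 with upper-quartile factors (9 higher) and 3 among genes above the median gene. DBP in the tumour averaged no more than the negative-probe level.

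HS epidermis (3 regions) was compared with healthy epidermis (3 regions) to see how the surface skin of HS differs from normal skin. SERPINB4 averaged 1260 ± 1049 against 12.7 ± 2.57 CPM (6.6 ± 1.21, edgeR adjusted p = 0.0365) and GJB2 2351 ± 1973 against 32.17 ± 2.543 CPM (6.2 ± 1.21, edgeR adjusted p = 0.0446). S100A9 (6.34 ± 1.49, edgeR adjusted p = 0.0979), PI3 (5.88 ± 1.3, edgeR adjusted p = 0.0893) and KRT6A (7.01 ± 1.77, edgeR adjusted p = 0.118) missed the threshold. SYT8 (-2.66 ± 0.43), the metallothionein MT4 (-2.09 ± 0.4), TNNI2 (-2.06 ± 0.35) and NINJ1 (-1.59 ± 0.3) were lower. CD200R1 (-1.46 ± 0.28), COL16A1 (-1.16 ± 0.22), HAUS7 (-1.16 ± 0.21) and POLR2M (-1.14 ± 0.2) made up the 10 genes changed, 2 higher and 8 lower. Wound keratin genes rose for 1 of 13 members (12 adjusted over the list alone). For wound keratins, camera gave adjusted p = 2.21e-14, and adjusted p = 0.21 with an estimated correlation. Antimicrobial genes passed for 0 of 24 (10 higher, adjusted over the list alone). For antimicrobial genes, camera gave adjusted p = 4.91e-12, and adjusted p = 0.21 with an estimated correlation. The count of 10 was 6 without healthy replicate 2, 0 without replicate 3, 0 without HS epidermis replicate 1, 41 without replicate 2 and 0 without replicate 3. None of the 10 genes kept the call in every one of the 6 fits, though 10 kept it without HS epidermis replicate 2 and 5 each without healthy replicate 1 or 2. The split turned to 25 higher and 3 lower of 28 with slide as a fixed block, and to 15 higher and 5 lower of 20 in a fit of only these groups, each sharing 3 genes with the 10. The count was 152 by DESeq2, 0 on the authors' values and 4 with upper-quartile factors. SERPINB4 in healthy epidermis lay under the negative-probe level of 13.98 CPM, and 7 of the 10 genes lay under 2 times that level in their lower group.

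Within HS, tunnel epithelium (11 regions) was compared with HS epidermis (3 regions), and 4 genes were lower in tunnels. KRT2 averaged 26.85 ± 20.63 against 1723 ± 2917 CPM (-5.94 ± 1.02, edgeR adjusted p = 0.023). In HS epidermis it was 5091 CPM in replicate 2 and 17.73 and 61.21 in the others, both within the tunnel range of 13.7 to 84.57, and it stood at -0.49 without replicate 2. That region also differed in KRT6A, at 137 CPM against 21940 and 8306. TGM3, a transglutaminase that cross-links the cornified envelope, averaged 28.1 ± 37.38 against 245.3 ± 117.7 CPM (-3.11 ± 0.52, edgeR adjusted p = 0.023). BLMH averaged 34.09 ± 24.01 against 319.9 ± 446.6 CPM (-3.16 ± 0.55, edgeR adjusted p = 0.023). LTF, the iron-binding antimicrobial lactoferrin, averaged 25.19 ± 5.105 against 65.32 ± 30.73 CPM (-1.38 ± 0.19, edgeR adjusted p = 0.00348). Cornified envelope genes fell for 1 of 18 members (1 adjusted over the list alone). For envelope genes, camera gave adjusted p = 1.01e-07, and adjusted p = 0.409 with an estimated correlation. Suprabasal genes fell for 1 of 11 (3 adjusted over the list alone). For suprabasal genes, camera gave adjusted p = 3.36e-07, and adjusted p = 0.191 with an estimated correlation. These 4 genes were all that changed by edgeR (25 by DESeq2, 0 on the authors' values), and 0 of them kept the call in every fit with a region left out. Without HS epidermis replicate 2, where KRT2, BLMH and TGM3 lost the call, and without mid tunnel replicate 1, 3 or 4, 1 gene was left. The count was 0 with slide as a fixed block, 0 within slide 1_3 and 0 with mid tunnel regions alone.

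Deep tunnel regions (7) were compared with mid tunnel regions (4) to see whether the tunnel differs along its depth. By edgeR 0 genes changed (317 at an unadjusted p under 0.05), and 0 by DESeq2 and on the authors' values. The neutrophil chemoattractants CXCL6 (-3.09 ± 0.94) and CXCL8 (-2.2 ± 0.7), DEFB4B (-2.54 ± 0.85) and the epithelial cytokine IL36G (-1.4 ± 0.45) had lower values in deep tunnels, each with an edgeR adjusted p = 1. Antimicrobial genes passed for 0 of 24 (5 lower, adjusted over the list alone), at a median log2 fold change of -0.82. For antimicrobial genes, camera gave adjusted p = 4.47e-10, and adjusted p = 0.328 with an estimated correlation. Cell cycle genes passed for 0 of 25 (0 adjusted over the list alone), with 24 values above 0 and a median of 0.29. For cycle genes, camera gave adjusted p = 6.65e-05, and adjusted p = 0.535 with an estimated correlation. In simulated counts of this comparison 98% of 4-fold and 68% of 2-fold changes were recovered. Those changed genes were drawn at random, 100 at each fold, and the simulated regions were independent. The shares therefore do not hold for variable genes such as CXCL6 and DEFB4B, or for regions that share a donor.

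Tunnel stroma (6 regions) was compared with SCC stroma (3 regions) to ask how the surroundings of the epithelium differ. IGKC averaged 50390 ± 27260 against 29.7 ± 18.89 CPM (10.69 ± 1.03, edgeR adjusted p = 1.27e-06), the lowest tunnel stroma region standing 420 times above the highest SCC stroma region. IGHG1 to IGHG4 ranged from 10.29 to 10.82, with IGLL5 at 9.03 ± 1.04 and IGHA1 at 7.58 ± 1.07. MZB1, a chaperone of antibody secretion, averaged 465.4 ± 207 against 28.19 ± 15.58 CPM (4.07 ± 0.58, edgeR adjusted p = 0.000403). XBP1, the transcription factor of the secretory programme (3.55 ± 0.54), and the sodium channel gene SCN9A (4.87 ± 0.7) rose with it. SCC stroma had more smooth muscle actin, ACTA2, at 343 ± 212.4 against 81.37 ± 32.45 CPM (-2.15 ± 0.34, edgeR adjusted p = 0.00105). It also had more of the basement membrane collagens COL4A1 (-2.65 ± 0.64), COL4A2 (-2.53 ± 0.58) and COL15A1 (-2.52 ± 0.39), of tenascin, TNC (-2.95 ± 0.73), and of FABP4 (-2.54 ± 0.4). Haemoglobin HBA2 (-3.03 ± 0.61), the protease gene CTSG (-2.13 ± 0.41), the sweat peptide gene DCD (-2.22 ± 0.37) and PITX1 (-2.13 ± 0.25) were lower in tunnel stroma too. Plasma cell genes rose for 16 of 20 members (20 adjusted over the list alone). For plasma cells, camera gave adjusted p = 1.87e-95, and adjusted p = 5.46e-05 with an estimated correlation. Secretory and unfolded-protein genes rose for 6 of 19 (8 adjusted over the list alone). For secretory genes, camera gave adjusted p = 2.38e-14, and adjusted p = 0.224 with an estimated correlation. Mural and smooth muscle genes fell for 4 of 10 (5 adjusted over the list alone), among them TAGLN (-2.09 ± 0.37). For mural genes, camera gave adjusted p = 1.39e-08, and adjusted p = 0.0651 with an estimated correlation. Invasion genes fell for 4 of 24 (7 adjusted over the list alone), among them the integrin gene ITGAV (-1.55 ± 0.33). For invasion genes, camera gave adjusted p = 3.9e-05, and adjusted p = 0.416 with an estimated correlation.

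In all 226 genes changed between tunnel and SCC stroma, 56 higher and 170 lower. The count was 36 without SCC stroma replicate 1, 55 without replicate 3 and 143 without deep tunnel stroma replicate 3. Of the 20 top genes 13 kept the call without each of 9 regions. DESeq2 called 435 genes, genes above the median gene gave 405, a fit of only these groups 142, mid tunnel stroma alone 66 and the authors' values 979, of which 740 were higher. DCD in tunnel stroma averaged no more than the negative-probe level. The groups shared no slide, so slide and diagnosis cannot be told apart.

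Cyst stroma (2 regions) gave the benign reference for tunnel stroma (6 regions), and plasma cell RNA again differed most. IGKC averaged 50390 ± 27260 against 30.78 ± 18.05 CPM (10.63 ± 1.25, edgeR adjusted p = 2.45e-05) and MZB1 465.4 ± 207 against 13.57 ± 12.83 CPM (5.04 ± 0.74, edgeR adjusted p = 0.000363). The cyst stroma mean of MZB1 lay under the negative-probe level of 14.43 CPM, and 11 of the 20 top genes lay under 2 times that level in their lower group. IGHG1 to IGHG4 ranged from 9.8 to 10.23, with IGLL5 (9.47 ± 1.28), IGHA1 (7.67 ± 1.3), SCN9A (4.62 ± 0.81) and JCHAIN, which joins IgA and IgM units (4.39 ± 0.87). Cyst stroma had more of the matrix genes POSTN, periostin (-3.03 ± 0.67), MMP11 (-2.88 ± 0.53), HTRA3 (-2.73 ± 0.27), HTRA1 (-2.69 ± 0.62) and MXRA8 (-2.34 ± 0.43). The early-response factor NR4A1 (-3.2 ± 0.3), LMNA (-2.39 ± 0.31), PLA2G2A (-3.28 ± 0.57) and CCDC87 (-4.31 ± 0.47) were lower in tunnel stroma too. The keratinocyte gene FLG, filaggrin, averaged 22.31 ± 17.36 in tunnel stroma against 256 ± 307.9 CPM (-3.63 ± 0.5, edgeR adjusted p = 0.000153). Plasma cell genes rose for 14 of 20 (19 adjusted over the list alone). For plasma cells, camera gave adjusted p = 3.03e-69, and adjusted p = 0.000277 with an estimated correlation. Cornified envelope genes, markers of keratinocytes, fell for 4 of 18 (8 adjusted over the list alone). For envelope genes, camera gave adjusted p = 1.93e-06, and adjusted p = 0.228 with an estimated correlation. Of 10 mural genes RGS5 (-1.88 ± 0.36) and NOTCH3 (-1.59 ± 0.29) fell (3 adjusted over the list alone). For mural genes, camera gave adjusted p = 3.07e-05, and adjusted p = 0.219 with an estimated correlation. Of 14 endothelial genes 3 fell, EGFL7 (-1.22 ± 0.29), CDH5 (-1.05 ± 0.27) and ESAM (-1.06 ± 0.27), with 4 adjusted over the list alone. For endothelial genes, camera gave adjusted p = 0.000126, and adjusted p = 0.219 with an estimated correlation.

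In all 224 genes changed between tunnel and cyst stroma, 53 higher and 171 lower. The count was 36 without cyst stroma replicate 1 and 142 without mid tunnel stroma replicate 1, and 10 of the 20 top genes kept the call without each of 8 regions. With 1 cyst stroma region left out the lone other one was assumed to vary like the other groups. DESeq2 called 426 genes, mid tunnel stroma alone 96 and the authors' values 518, of which 349 were higher. The groups shared no slide.

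**Figure D3:**
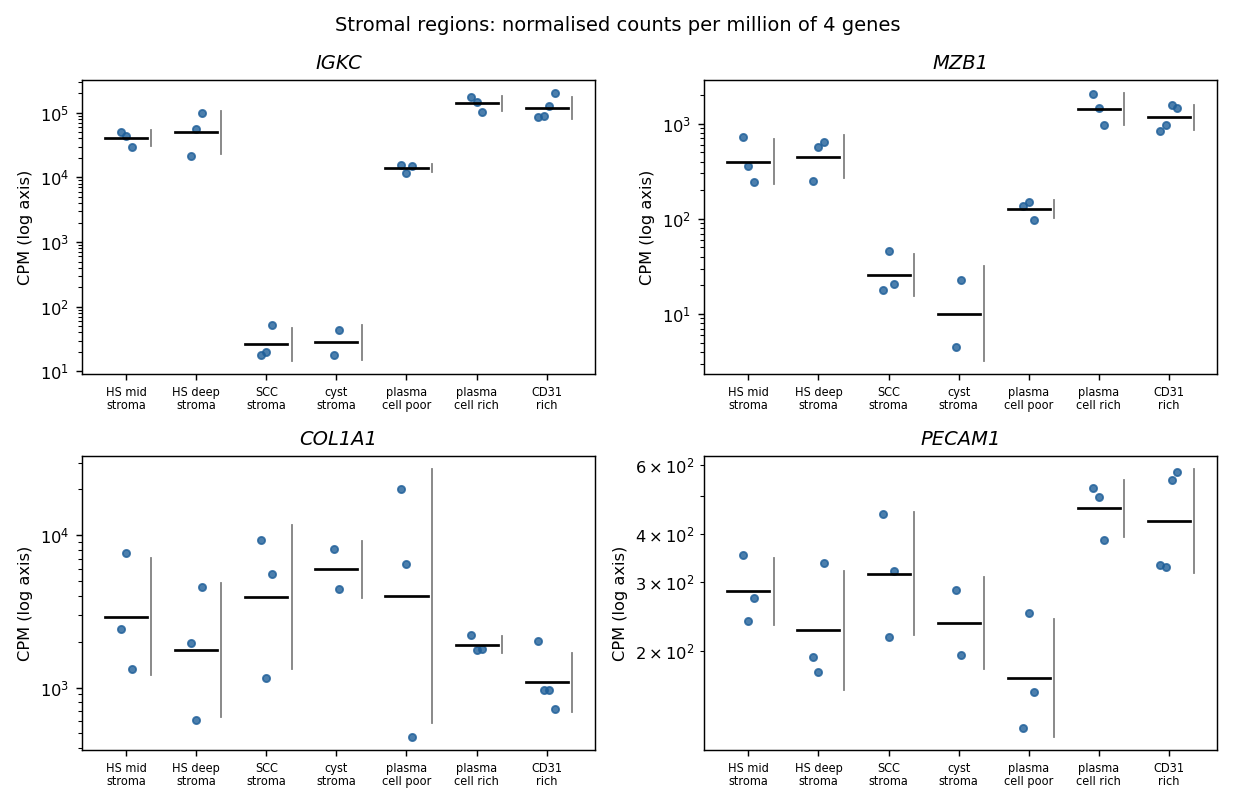
CPM (log axis, TMM-scaled) of IGKC, MZB1, COL1A1 and PECAM1 in each stromal region by group; points are regions, the black line is the geometric mean and the grey bar spans 1 SD of log2 CPM on either side. IGKC averaged 29.7 CPM in SCC stroma, 30.78 in cyst stroma, 50390 in tunnel stroma, 14070 in plasma cell poor and 142000 in plasma cell rich stroma.

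Plasma cell rich and plasma cell poor HS stroma (3 regions each, all on 1 slide) were compared to describe the infiltrate the regions were chosen for. MZB1 averaged 1493 ± 546.7 against 127.5 ± 26.18 CPM (3.55 ± 0.55, edgeR adjusted p = 0.000767). IRF4, a transcription factor plasma cells need, averaged 664.6 ± 249.3 against 64.15 ± 12.23 CPM (3.37 ± 0.45, edgeR adjusted p = 0.000374). XBP1 (3.28 ± 0.55), IGKC (3.33 ± 0.75), IGHG2 to IGHG4 (3.33 to 3.38), SCN9A (3.51 ± 0.63), IGHA1 (3.17 ± 0.86) and IGLL5 (3.16 ± 0.79) rose too. SFRP4, a fibroblast-made WNT antagonist, was lower in the rich regions at 22.31 ± 2.483 against 216 ± 234.5 CPM (-3.26 ± 0.53, edgeR adjusted p = 0.00106). The matrix genes CILP (-2.63 ± 0.35), COL14A1 (-2.47 ± 0.54), OGN (-2.42 ± 0.45), CCDC80 (-2.42 ± 0.67) and FBLN1 (-2.07 ± 0.49) fell with it. IGFBP5 (-3.98 ± 1.03), the chemokine gene CXCL14 (-3.29 ± 0.88), PLA2G2A (-3.06 ± 0.66) and CLU (-2.64 ± 0.63) were lower as well. Plasma cell genes rose for 18 of 20 (19 adjusted over the list alone). Their camera adjusted p was 1.62e-37, with adjusted p = 0.00606 with an estimated correlation. Secretory and unfolded-protein genes rose for 15 of 19 (19 adjusted over the list alone), for example HERPUD1 (2.72 ± 0.46) and DNAJB9 (2.12 ± 0.34). For secretory genes, camera gave adjusted p = 7.52e-28, and adjusted p = 0.0624 with an estimated correlation. Collagen and cross-linking genes fell for 4 of 23 (10 adjusted over the list alone), among them ELN, elastin (-1.7 ± 0.41), and LOX, which cross-links collagen (-1.35 ± 0.34). For collagen genes, camera gave adjusted p = 1.92e-05, and adjusted p = 0.746 with an estimated correlation. The regions were chosen by staining for the protein of SDC1 (1.71 ± 0.4), so it and the plasma cell list are no independent finding. The 10 most abundant genes took 50.91 to 57.78% of counts in rich and 12.34 to 19.54% in poor regions.

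In all 642 genes changed between rich and poor stroma, 365 higher and 277 lower (1069 by DESeq2, 392 on the authors' values). The split turned to 324 higher and 362 lower with upper-quartile factors, 342 and 417 without poor replicate 2 and 202 and 215 without poor replicate 3. On background-subtracted values (chosen after seeing the data) 54 were higher and 1320 lower, where the median of all genes was itself -0.457. The negative-probe level was 26 CPM in poor replicate 3 and 13.01 and 13.83 in the other poor regions. The count was 417 without plasma cell poor replicate 3, 314 without rich replicate 1 and 302 without rich replicate 2. Of the 20 top genes 9 kept the call without each of the 6 regions.

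CD31 rich HS stroma (4 regions), chosen by the vessel stain, was compared with the same plasma cell poor regions (3). Of 14 endothelial genes 1 rose (1 adjusted over the list alone), PECAM1 (1.32 ± 0.38, edgeR adjusted p = 0.0442), the gene of the stained protein. It was also higher in plasma cell rich than in the same poor regions (1.39 ± 0.4, edgeR adjusted p = 0.0455), at 468.4 ± 74.19 CPM against 446.3 ± 133.4 in CD31 rich stroma. It lost the call without CD31 rich replicate 3 or 4, or without poor replicate 1 or 3. After background subtraction (chosen after seeing the data) PECAM1 stood at 0.16, where the median of all genes was itself -0.442. The endothelial transcription factor gene ERG stood at -0.25 ± 0.22 (edgeR adjusted p = 0.584). For endothelial genes, camera gave adjusted p = 0.891, and adjusted p = 0.975 with an estimated correlation. IGKC averaged 125500 ± 53000 against 14070 ± 2081 CPM (3.16 ± 0.72, edgeR adjusted p = 0.0109) and MZB1 1202 ± 354.6 against 127.5 ± 26.18 CPM (3.24 ± 0.53, edgeR adjusted p = 0.00139). DERL3, which clears misfolded proteins (3 ± 0.49), XBP1 (2.85 ± 0.53), IGHG1 to IGHG4 (2.91 to 3.07), IGLL5 (2.96 ± 0.76) and IGHA1 (2.87 ± 0.83) rose too. CILP, a matrix gene, was lower (-2.73 ± 0.31, edgeR adjusted p = 4.7e-05). Collagen and cross-linking genes fell for 9 of 23 (16 adjusted over the list alone), among them the chains COL1A1 (-2.96 ± 0.87, edgeR adjusted p = 0.0491) and COL1A2 (-3.01 ± 0.78). For collagen genes, camera gave adjusted p = 6.26e-09, and adjusted p = 0.473 with an estimated correlation. COL1A1 was 20210, 6508 and 475.7 CPM in the 3 poor regions, the last under all 4 CD31 rich regions, and lost the call without poor replicate 1 or 2 or CD31 rich replicate 2, 3 or 4. SFRP4 (-2.91 ± 0.45), SFRP2 (-2.88 ± 0.77), IGFBP5 (-3.28 ± 0.88) and HTRA1 (-3.19 ± 0.66) fell too, with PLA2G2A (-3 ± 0.58), CTHRC1 (-2.81 ± 0.73) and CCDC80 (-2.73 ± 0.6). Plasma cell genes rose for 18 of 20 (20 adjusted over the list alone). Their camera adjusted p was 1.87e-36, with adjusted p = 0.00759 with an estimated correlation. The reference regions were chosen as poor in plasma cells, so the higher plasma cell and immunoglobulin genes here are no independent finding. Secretory genes rose for 15 of 19 (19 adjusted over the list alone). For secretory genes, camera gave adjusted p = 2.31e-27, and adjusted p = 0.0706 with an estimated correlation.

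In all 691 genes changed between CD31 rich and plasma cell poor stroma, 304 higher and 387 lower, which turned to 367 and 310 without CD31 rich replicate 2 and to 196 and 162 on the authors' values. The count was 386 without CD31 rich replicate 3, 360 without replicate 4 and 391 without plasma cell poor replicate 1, and 6 of the 20 top genes kept the call without each of the 7 regions. DESeq2 called 1101 genes, the authors' values 358 and a fit of only these groups 416.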

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

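No test in this part was chosen after its result was seen. Each group of 4 to 10 regions was searched for single regions far from the others in a named gene, with Dixon's test at 1 in 20. Of 127 groups and values tested 11 stood out, against 6.3 expected by chance, and the values are log2 CPM. In CD31 rich stroma CTHRC1, a matrix gene, was 7.47 in replicate 1 (5.15 to 5.5 in the others), and CILP was 4.97 in replicate 3 (4.27 to 4.35). In deep tunnel replicate 1 S100A7 was 11.2 (13.4 to 14.8 in the others) and SERPINE2 6.53 (4.05 to 5.1), and in replicate 2 PADI1 was 6.7 (3.7 to 4.76). In mid tunnel replicate 4 NFKBIZ was 8.03 (6.36 to 6.62), RCAN1 5.21 (5.64 to 5.72) and TNFRSF11B 2.21 (4.02 to 4.1). In mid tunnel replicate 2 the cornification genes BLMH and TGM3 were 6.74 (4.62 to 4.86) and 7.14 (3.89 to 4.29). In mid tunnel replicate 1 SPINK6 was 4.65 (4.54 to 4.55). No biological explanation was tested for these values.

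The infundibulum, the upper part of the hair follicle, had 1 region in HS and 1 in a cyst and entered no comparison. All 10 of the top genes of tunnel over healthy epidermis stood above the highest of the 3 healthy regions in the HS infundibulum, and 10 in the cyst infundibulum. Levels here are CPM without TMM factors. KRT6A was 168 times the highest healthy region in the HS infundibulum and 36.4 times in the cyst infundibulum, and S100A9 37 and 34.8 times. DEFB4B was 92.9 and 1.24 times, and PI3 50 and 1.58 times. Neither region has a replicate, so the difference between them was not tested.

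Other splits of the same regions into groups of the same sizes were refitted to see how many genes chance regroupings call. Regions that share a donor are not exchangeable, which these splits ignore. For tunnel against healthy epidermis, 1 of 100 splits, the real one, gave as many as 675 genes (highest other 86). For tunnel against SCC it was 1 of 100 (78 genes, highest other 69), for tunnel against cyst wall 1 of 100 (164, highest other 100), for tunnel against SCC stroma 1 of 84 (226, highest other 12) and for CD31 rich against plasma cell poor 1 of 35 (691, highest other 183). In these comparisons no other split drawn reached the real count. Chance is not excluded by this, since regions of 1 donor are not exchangeable. Of the 364 possible splits of each of these tunnel epithelium comparisons only 100 were drawn. For tunnel against HS epidermis 20 of 100 splits gave as many as the 4 genes, so chance cannot be excluded. The highest other split called 581, at a median of 0 over the other splits, and what set it apart was not tested. For deep against mid tunnel the real count was 0, which all 100 splits reach by construction (highest other 96), so these splits say nothing about chance there.

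With 10 splits no share under 0.05 is possible, which holds for the comparisons of 3 with 3 regions. Of the 10 splits 1 reached the real count for SCC against healthy epidermis (304, highest other 34) and 1 for plasma cell rich against poor (642, highest other 0). For HS epidermis against healthy epidermis 3 of 10 did (10 genes, highest other 16). For cyst wall against healthy epidermis the real count was 0, which all 10 splits reach by construction (highest other 40). For SCC against cyst wall 2 of 10 did (29 genes). The highest other split called 448, at a median of 0 over the other splits, and what set it apart was not tested. The count was made where each group had at least 3 regions, so it was not made for cyst stroma.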

How the results depend on the processing

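Chosen after seeing the data were the fits without regions under 200000 counts, on background-subtracted values and by limma-voom without a slide block, and the similarity when thinned, without shallow regions, background-subtracted and without plasma cell genes. All other alternatives were planned. No paired analysis was possible because the labels give no replicate or donor numbers that tie a region of one group to a region of another. The filter removed no gene, so the fit with no filter is identical and tests nothing. Slide as a random block could not be fitted among stromal groups, each of which lies on 1 slide. Where a count moved, the cause was not tested unless the alternative itself uses fewer regions or genes.

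Of 4775 alternative values of 296 changed gene results, 3720 kept direction and threshold, 1051 kept the direction and missed the threshold, and 4 reversed. BTG4, HS tunnel epithelium vs healthy epidermis (-2.82), was 0.23 without regions under 200000 counts and ran from -3.68 to 0.22 with a region left out, 0.22 being without healthy epidermis replicate 2. TNFRSF11B, HS tunnel epithelium vs cyst wall (-5.27), was 0.72 without regions under 200000 counts and ran from -5.91 to 0.74 with a region left out, 0.74 being without cyst wall replicate 1. No named gene reversed with upper-quartile factors, with DESeq2, on the authors' values or after background subtraction. Past the threshold in every setting were 10 of 45 named genes for tunnel against healthy epidermis, 8 of 21 for tunnel against SCC, 7 of 21 for tunnel against cyst wall, 3 of 26 for SCC against healthy epidermis and 0 of 16 for SCC against cyst wall. In HS it was 0 of 10 for HS epidermis against healthy epidermis and 0 of 4 for tunnel against HS epidermis, and in stroma 13 of 31 (SCC), 10 of 42 (cyst), 14 of 37 (plasma cell rich) and 17 of 43 (CD31 rich). Of 157 list calls by camera, 5 held with an estimated correlation, all of the plasma cell list. Among them are plasma cell rich and CD31 rich against plasma cell poor stroma, where regions were chosen for plasma cells, so these are no independent finding.

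By DESeq2 the counts were 1261 for tunnel against healthy epidermis (675 by edgeR), 799 for SCC against healthy epidermis (304), 72 for cyst wall against healthy epidermis (0), 190 for tunnel against SCC (78) and 414 for tunnel against cyst wall (164). They were 270 for SCC against cyst wall (29), 152 for HS epidermis against healthy epidermis (10), 25 for tunnel against HS epidermis (4), 435 and 426 for tunnel stroma against SCC and cyst stroma (226 and 224), 1069 for plasma cell rich (642) and 1101 for CD31 rich (691). The split of higher to lower genes was 611 to 650 for tunnel against healthy epidermis, 55 to 135 against SCC, 125 to 289 against cyst wall and 11 to 14 against HS epidermis, 79 to 191 for SCC against cyst wall and 52 to 100 for HS epidermis against healthy epidermis.

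On the authors' values, in the same order, the epithelial counts were 1218, 475, 203, 17, 615, 154, 0 and 0, and the stromal counts 979, 518, 392 and 358. Their direction moved with the scaling: 729 higher and 489 lower for tunnel against healthy epidermis, 301 and 174 for SCC, 10 and 7 for tunnel against SCC, 136 and 18 for SCC against cyst wall (12 and 17 by edgeR), 740 and 239 for tunnel against SCC stroma, 349 and 169 against cyst stroma and 196 and 162 for CD31 rich. The median of all genes shifted by -0.169 for cyst wall against healthy epidermis, 0.149 for tunnel and 0.182 for SCC against cyst wall, 0.145 for tunnel against SCC stroma and -0.134 for plasma cell rich.

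On background-subtracted values the epithelial counts were 4095 (453 higher), 3054 (291), 10 (1), 23 (14), 519 (45), 234 (16), 343 (29) and 1 (0), and the stromal counts 2760 (168), 2704 (149), 1374 (54) and 1401 (42), with median shifts from -0.531 to 0.158. With upper-quartile factors they were 55 (27 higher) for tunnel and 11 (9) for SCC against cyst wall and 4 (1) for HS epidermis, with median shifts of 0.166, 0.215 and under 0.1 in size. That scaling also shifted the median by -0.183 for cyst wall against healthy epidermis, 0.106 for tunnel against SCC stroma, -0.163 for plasma cell rich and -0.106 for CD31 rich, and turned the split of plasma cell rich to 324 higher and 362 lower, and of SCC against healthy epidermis to 167 and 137. The split was 98 to 129 for tunnel against SCC stroma and 80 to 130 against cyst stroma. Among the 7116 genes above the median gene the counts were 491 for SCC and 1 for cyst wall against healthy epidermis, 28 for tunnel against SCC, 87 for tunnel and 3 for SCC against cyst wall, 0 for tunnel against HS epidermis and 405 for tunnel against SCC stroma.

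In fits of only the groups compared the counts were 686 for SCC against healthy epidermis, 99 for tunnel and 14 for SCC against cyst wall, 20 for HS epidermis, 142 for tunnel against SCC stroma and 416 for CD31 rich. With mid tunnel regions alone they were 18 against SCC, 35 against cyst wall, 0 against HS epidermis, 66 against SCC stroma and 96 against cyst stroma, and with deep regions alone 371 against healthy epidermis, 48 against SCC and 61 against cyst wall. Without regions under 200000 counts they were 46 for cyst wall against healthy epidermis, 339 for tunnel and 101 for SCC against cyst wall and 32 for HS epidermis. With slide as a fixed block 0 genes changed for tunnel against HS epidermis and 28 (25 higher) for HS epidermis against healthy epidermis, while the 763 of tunnel against healthy epidermis held 475 higher. Within slide 3_2 tunnel against healthy epidermis gave 1443 (1008 higher), and within slide 1_3 tunnel against HS epidermis gave 0. With slide as a random block limma-voom called 327 genes for tunnel against cyst wall (176 without the block) and 103 for tunnel against SCC (42 without it), at a correlation within slides of -0.031. Deep against mid tunnel gave 0 in every alternative.

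With each region of a group of 2 to 5 left out in turn, the counts ran from 109 to 698 for tunnel, 37 to 247 for SCC and 0 to 306 for cyst wall against healthy epidermis, and from 45 to 121 for tunnel against SCC. They ran from 87 to 208 for tunnel and 1 to 108 for SCC against cyst wall, 0 to 41 for HS epidermis, 1 to 5 for tunnel against HS epidermis and 0 to 0 for deep against mid tunnel. In stroma they ran from 36 to 317 (SCC), 36 to 220 (cyst), 302 to 759 (plasma cell rich) and 360 to 719 (CD31 rich). The similarity difference of 0.0503 ran from 0.0351 to 0.0947. Correlations of fold changes ran from 0.817 to 0.847 for tunnel and SCC (0.816 with all regions), 0.607 to 0.701 for tunnel and cyst wall and 0.57 to 0.66 for SCC and cyst wall. Among genes above the median gene they were 0.838 for tunnel and SCC and 0.662 for SCC and cyst wall, and on the authors' values 0.848 for tunnel and SCC.

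The similarity difference kept its sign in each alternative: 0.0356 with Spearman rho (exact permutation p 0.6), 0.0923 over the most variable genes (0.1), 0.0733 over genes above the median gene (0.1), 0.047 on the authors' values (0.2), 0.0596 with mid (0.1) and 0.0409 with deep regions alone (0.2), and 0.0397 without shallow regions (0.1). The Euclidean distance to cyst wall exceeded that to SCC by 15.7 (0.1). No permutation p below 0.1 is possible here. The shallowest regions were 1 of healthy epidermis and 1 of cyst wall (134665 and 169820 counts), and SCC stroma (median 325116) and cyst stroma (366187 and 415440) were shallow as groups.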

Other observations

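Chosen after the data were seen were the tests of the similarity by thinning, by background subtraction and without plasma cell genes, the checks that voided the tests of a few abundant genes and of background in the split, and the spread over plasma cell genes. Markers of other cells moved in several comparisons. In tunnel over healthy epidermis the macrophage genes CD68 (2.32 ± 0.52, edgeR adjusted p = 0.0125) and CD14 (1.93 ± 0.49, edgeR adjusted p = 0.0244) rose and APOE fell (-2.52 ± 0.39, edgeR adjusted p = 0.000651). Of 16 macrophage genes these 3 passed (4 higher and 1 lower, adjusted over the list alone), with a camera adjusted p = 0.0102 and adjusted p = 0.77 with an estimated correlation. CD68 and CD14 lost the call without healthy replicate 1 or 3. CD3E, a part of the T cell receptor, rose by 1.58 ± 0.44 (edgeR adjusted p = 0.0371), as 1 of 16 T cell genes (1 adjusted over the list alone). For T cell genes, camera gave adjusted p = 0.145, and adjusted p = 0.86 with an estimated correlation. CD3E lost the call in several fits, among them with slide as a fixed block (1.16) and without healthy replicate 1 or 3 or mid tunnel replicate 1. The sebaceous lipid enzyme gene SCD rose by 3.26 ± 0.78 (edgeR adjusted p = 0.0176), as 1 of 9 sebaceous genes (2 higher and 1 lower, adjusted over the list alone), with camera adjusted p = 0.909 and adjusted p = 0.921 with an estimated correlation. The melanocyte enzyme gene DCT fell (-1.67 ± 0.48, edgeR adjusted p = 0.0463), as 1 of 8 melanocyte genes (2 adjusted over the list alone), with camera adjusted p = 0.00227 and adjusted p = 0.562 with an estimated correlation. SCD and DCT each lost the call without any 1 of the 3 healthy regions.

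CD79A, a part of the B cell receptor that plasma cells also express, was higher in tunnel stroma than in SCC stroma (2.83 ± 0.45, edgeR adjusted p = 0.00125) and cyst stroma (3.06 ± 0.54, edgeR adjusted p = 0.00279). It was also higher in plasma cell rich than poor stroma (2.52 ± 0.43, edgeR adjusted p = 0.00167), with the B cell gene TNFRSF13C (1.26 ± 0.26, edgeR adjusted p = 0.00563). The histamine-making enzyme gene HDC of mast cells was lower in rich than poor stroma (-1.05 ± 0.24, edgeR adjusted p = 0.013), 1 of 7 mast cell genes (4 lower, adjusted over the list alone). CD27, a receptor of T cells and plasma cells, was higher in rich stroma (1.78 ± 0.39, edgeR adjusted p = 0.00835) and in CD31 rich stroma (1.34 ± 0.37, edgeR adjusted p = 0.0335).

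Summed immunoglobulin RNA was 148 ± 22.4 CPM in SCC epithelium, 267 ± 131 in cyst wall, 928 ± 378 in healthy epidermis, 1470 ± 810 in HS epidermis, 5340 ± 4780 in deep and 8310 ± 5640 in mid tunnel epithelium. Counts carried between wells at one level did not explain the excess over SCC, since the median tunnel region held 11.2 times the immunoglobulin count of the highest SCC, cyst wall or healthy region; a carry-over that differs between wells was not tested. RNA of plasma cells in or beside the tunnel regions is a candidate explanation. The sum of 12 other plasma cell genes exceeded SCC by 1.87 times (SE 0.263 over regions, 0.554 over genes) the amount predicted from 7 immunoglobulin genes. For the prediction the immunoglobulin excess was read as a share of plasma cell rich stroma, 0.793% on average (0.204 to 2.09% by region). Levels in that stroma (MZB1 1490 and XBP1 3730 CPM) came from the separate stromal fit, so the share depends on the scaling of both fits. XBP1 (141 against 95.2 CPM) and SSR4 (186 against 130), which keratinocytes also express, made 69.2% of that excess, and without them the ratio was 1.29. MZB1 was 23.2 against 15.1 CPM, 2 genes (CD38 and SLAMF7) were lower in tunnels than in SCC, and single genes, many near the negative-probe level, ran from -6.4 (CD38) to 11.1 (JCHAIN) times. A difference between slides could not be told apart from the diagnosis, since tunnel and SCC share no slide, and the log2 excess of 3.38 of 2 tunnel over 3 healthy regions within slide 3_2 bears on healthy skin only, while a difference of the disease itself stays open.

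The similarity of tunnel epithelium was greater to SCC than to cyst wall by 0.0503, with a jackknife SE over the SCC and cyst wall regions of 0.0567. Without the 21 plasma cell and immunoglobulin genes the difference was 0.0517, so these genes themselves were not its source. So few genes can hardly move a correlation across all genes, and other RNA of plasma cells was left in. A part of such RNA in the difference was therefore not tested. Depth may contribute: with every region thinned to 117098 counts the difference was 0.0225 (SE 0.0457). After subtraction of the negative-probe level it was 0.0431. These moves are within the spread, so depth and background cannot be told apart from a likeness of the tissues, and neither can the slide.

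Of the genes called for tunnel against cyst wall 19.5% were higher in tunnels by edgeR, against 540 of 615 on the authors' values. Whether the background share of the counts set the split cannot be told: the 508 genes higher on the authors' values alone had a median log2 fold change of 1.15, 0.26 from the 0.89 of the negative-probe level, but they were selected as higher. Their median count stood 1.8 times above the negative-probe level, against 2 times for all genes. Whether a few abundant genes set the split cannot be told, since leaving out the 50 most abundant genes moved the TMM factors by at most 0.19% and the share stayed at 19.5%. A biological part of the split was not tested.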
